A study of Rattus norvegicus with 4 samples.

How the data were processed

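Chromatin immunoprecipitation sequencing (ChIP-seq) was done on cultured rat oligodendrocytes, the myelin-forming glia of the central nervous system, with 2 antibodies in 2 conditions. One antibody recognised H3K27Ac, an acetyl mark on histone H3 found at active promoters and enhancers. The other recognised Olig2, a basic helix-loop-helix transcription factor of the oligodendrocyte lineage. Per the labels' protocols, mixed glia were grown for 5 to 7 days and then for 2 days in B104 medium, after which oligodendrocyte precursors were isolated, expanded with PDGF-AA and bFGF, and differentiated with thyroid hormone T3 at 15 nM and ciliary neurotrophic factor at 10 ng/ml. Cells received lysolecithin (lysophosphatidylcholine, LPC, a detergent-like lipid used to demyelinate tissue) for 6 h, or vehicle. The labels give the LPC concentration as 12.5 mM, and that value is repeated here as given. Whether millimolar or micromolar was meant was not established from the sources used here, so the dose is uncertain. Per the labels' protocols, libraries were made from sonicated nuclei and run on a SOLiD sequencer.

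The authors deposited 1 peak list per library, with 3 columns (chromosome, start and end) and no score, height, fold or p-value. The submitters' processing notes name MACS version 1.4.2 and the rat build rn4. The peak threshold, the control library, the aligner, the read depth and any splitting of peaks are not given in the sources used here. Each list came from a single sample. Because the lists hold no read counts, the depth behind a peak is unknown, a peak missing from a list may lie just under that list's threshold, and signal cannot be compared between conditions. Peak length stands in for rank within a list where a rank was needed, and it also depends on the depth, the enrichment and the caller.

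Lists were compared by overlap of at least 1 bp with interval code in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1). The code was checked against bedtools 2.31.1, with a difference of 0 peaks in each comparison of counts. It was also tested on simulated lists with known sharing. It recovered 100% of the shared peaks made for 38902 simulated H3K27Ac peaks and 100% for 4966 simulated Olig2 peaks, and the mean of the position shifts was 0.94 and 1.02 times the calculated expectation. The simulated peaks were of equal length and widely spaced, and shared ones were made to overlap. The simulation therefore checked the code and not the handling of split or closely spaced peaks. A peak was called shared when it overlapped a peak of the same antibody in the other condition, and vehicle-only or LPC-only otherwise. Since peaks can be split in one list and whole in the other, the number of shared peaks differs between the lists of one antibody. The expectation without any relation came from 1000 shifts of one list round each chromosome by a random distance. Shares carry exact binomial (Clopper-Pearson) 95% intervals, and differences of shares carry Newcombe intervals built from Wilson limits. These cover counting error only, treat neighbouring peaks as independent and say nothing about variation between cultures. With 1 library per antibody and condition there was no replicate, so no p-value was computed and no setting could leave out a replicate.

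H3K27Ac peaks at most 12.5 kb apart were joined into domains. H3K27Ac peaks with an Olig2 peak were also compared with 1000 random draws of peaks without one, matched on length in 20 bins. Regions named in the text followed a rule fixed before the data were examined: the 5 longest peaks of each class (length replacing the score that the lists lack), the 5 longest domains per condition, and any of the 10 longest condition-only Olig2 peaks that overlapped an H3K27Ac peak only in the same condition. Shared peaks were ranked by their length in the vehicle list. Coordinates are 1-based on rn4.

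The gene lists fixed beforehand (myelin and mature oligodendrocyte, precursor, lipid synthesis, immediate early, stress, inflammation, p53 and apoptosis, other cell types and housekeeping) were not analysed here. An annotation of rn4 was not used here, and the gene table at hand describes another rat assembly, so peaks were not assigned to genes, exons or promoters. Alternatives planned beforehand were a reciprocal overlap of 50%, counting peaks within 1 kb as overlapping, autosomes alone, and joining distances of 5 and 25 kb. Filters on score could not be run and were replaced by filters on length. Those filters, joining peaks within 1 kb, joining combined with the reciprocal overlap, shifts of 50 to 500 kb and the length-matched draws were added after the lists had been seen.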

Results

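The series comprised 4 ChIP-seq libraries from differentiated rat oligodendrocyte cultures, 1 for each combination of antibody (H3K27Ac or Olig2) and condition (vehicle or 6 h of LPC). Its stated purpose was to examine where H3K27Ac and Olig2 sit on the oligodendrocyte genome, and the comparison implied by the design is LPC against vehicle for each antibody. The vehicle H3K27Ac list held 38902 peaks covering 34.4 Mb, and the LPC H3K27Ac list held 38721 peaks covering 41.7 Mb. The vehicle Olig2 list held 4965 peaks covering 5.68 Mb, and the LPC Olig2 list held 3229 peaks covering 3.50 Mb. Peaks lay on 20 autosomes and X in every list. Read depth was unknown, and every comparison below is between single libraries.

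Fewer Olig2 peaks were called after LPC, and almost all of them lay at sites already called in vehicle. Without depths or scores, lower occupancy cannot be told apart from lower yield. Of the 3229 LPC Olig2 peaks, 3181 (98.5%, 95% interval 98.0 to 98.9) overlapped a vehicle Olig2 peak, and 48 did not. Of the 4965 vehicle Olig2 peaks, 3180 (64.0%, 62.7 to 65.4) overlapped an LPC peak, and 1785 (36.0%, 34.6 to 37.3) were vehicle-only. The matched peaks were nearly equal in number (3180 and 3181), so the condition-only counts differ nearly as the list lengths do. With the vehicle list shifted along the chromosomes, a mean of 0.29% of its peaks overlapped the LPC list, and the highest of 1000 shifts gave 2.96%. Cutting the vehicle list to its 3229 longest peaks, the size of the LPC list, gave 995 vehicle-only and 994 LPC-only peaks, because lists of equal size leave nearly equal remainders.

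The sites missing from the LPC Olig2 list were spread over all peak lengths and all chromosomes. The share of vehicle Olig2 peaks kept was 51.7% (48.5 to 54.8) in the shortest 20% of the list and 71.9% (69.0 to 74.7) in the longest 20%. Between autosomes it ran from 58.5% on chromosome 15 to 74.3% on chromosome 16. Vehicle-only Olig2 peaks had a median length of 987 bp, against 1090 bp for shared ones. Among the 3176 vehicle Olig2 peaks with a single LPC partner, the LPC peak was the longer one in 29.8%, and the median ratio of lengths (LPC over vehicle) was 0.93.

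**Figure D1:**
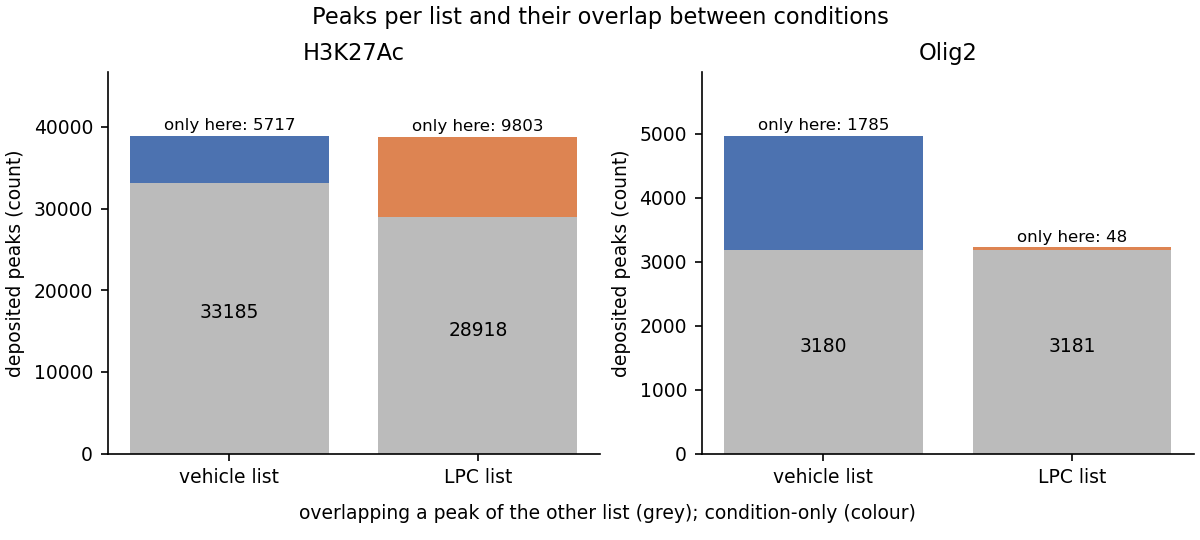
Number of deposited peaks (vertical axes, linear, from 0) in the vehicle and LPC lists of H3K27Ac (left) and Olig2 (right). Grey marks peaks that overlap the other condition's list by at least 1 bp and colour marks condition-only peaks: 5717 and 9803 for H3K27Ac, 1785 and 48 for Olig2.

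The longest vehicle-only Olig2 peak lay on chromosome 14 (4362813 to 4368029, 5217 bp). It was the only one of the 10 longest vehicle-only Olig2 peaks that overlapped a vehicle-only H3K27Ac peak. Vehicle H3K27Ac peaks covered 4878 bp of it and LPC H3K27Ac peaks 1232 bp. The next longest were on chromosome 2 (120977299 to 120980803), chromosome 15 (66388595 to 66391773), chromosome 7 (72973919 to 72976868) and chromosome 3 (8814284 to 8816969). Those sites were acetylated in both lists. The chromosome 2 site, for example, was covered over its full 3505 bp by H3K27Ac peaks in vehicle and in LPC.

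The longest of the 48 LPC-only Olig2 peaks lay on chromosome 6 (39493014 to 39496230, 3217 bp), and all of it was covered by H3K27Ac peaks in both conditions. The LPC-only Olig2 peak on chromosome 5 (101398628 to 101401673, 3046 bp) had 2788 bp covered by H3K27Ac peaks in vehicle and 2397 bp in LPC. Those on chromosome 7 (22728322 to 22730880), chromosome 17 (49586334 to 49588747) and chromosome 2 (13420634 to 13422545) also lay on peaks of both H3K27Ac lists. None of the 10 longest LPC-only Olig2 peaks overlapped an LPC-only H3K27Ac peak.

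The longest shared Olig2 peaks were on chromosome 5 (22750285 to 22754354), chromosome 2 (1283810 to 1287756), chromosome 13 (49500518 to 49504143), chromosome 20 (41309620 to 41312977) and chromosome 18 (49957480 to 49960743). The one on chromosome 2, 3947 bp long in vehicle, carried no H3K27Ac peak in either condition. The other 4 carried H3K27Ac peaks in both.

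H3K27Ac peaks were largely shared between the conditions. The LPC list held longer peaks, in nearly the same number, and more of them were condition-only. Of the vehicle peaks, 33185 (85.3%, 84.9 to 85.7) overlapped an LPC peak, and 5717 were vehicle-only. Of the LPC peaks, 28918 (74.7%, 74.2 to 75.1) overlapped a vehicle peak, and 9803 were LPC-only, 1.71 times the vehicle-only number. In 1000 shifts, at most 3.97% of vehicle peaks overlapped the LPC list. The median peak length was 674 bp in vehicle (quartiles 490 and 1042 bp) and 823 bp in LPC (555 and 1341 bp).

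The vehicle H3K27Ac list was also the more finely divided one. In it, 32.0% of peaks had another peak within 500 bp downstream, against 26.0% in the LPC list and under 1% in either Olig2 list. Joining peaks within 1 kb left 25115 vehicle and 27457 LPC regions, spanning 37.2 and 43.9 Mb. Of these, 3870 were vehicle-only and 6443 LPC-only. The median length of the joined regions was 1161 bp in vehicle and 1295 bp in LPC, a ratio of 1.12, against 1.22 for the unjoined peaks. When at least 50% of each peak had to overlap, 16891 vehicle-only and 16710 LPC-only peaks remained in the unjoined lists. In the joined ones 7960 and 10302 remained. That rule matches peaks 1 to 1, so each pair of remainders differs only as the list lengths do. These counts are therefore no separate check on the excess of LPC-only peaks.

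When both lists were pooled and joined within 1 kb, 30760 acetylated regions resulted. Of these, 21354 held peaks of both conditions, 3395 of vehicle alone and 6011 of LPC alone. In 71.8% of the regions with both, LPC peaks covered more bases than vehicle peaks, and the median ratio of covered length was 1.15.

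Condition-only H3K27Ac peaks were short. Their median lengths were 478 bp for vehicle-only and 531 bp for LPC-only peaks, against 740 bp and 1003 bp for shared peaks of the same lists. In the longest 20% of the lists, 99.6% of vehicle and 99.1% of LPC peaks were shared. In the shortest 20% the shares were 67.9% (66.8 to 68.9) and 41.7% (40.6 to 42.8).

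**Figure D2:**
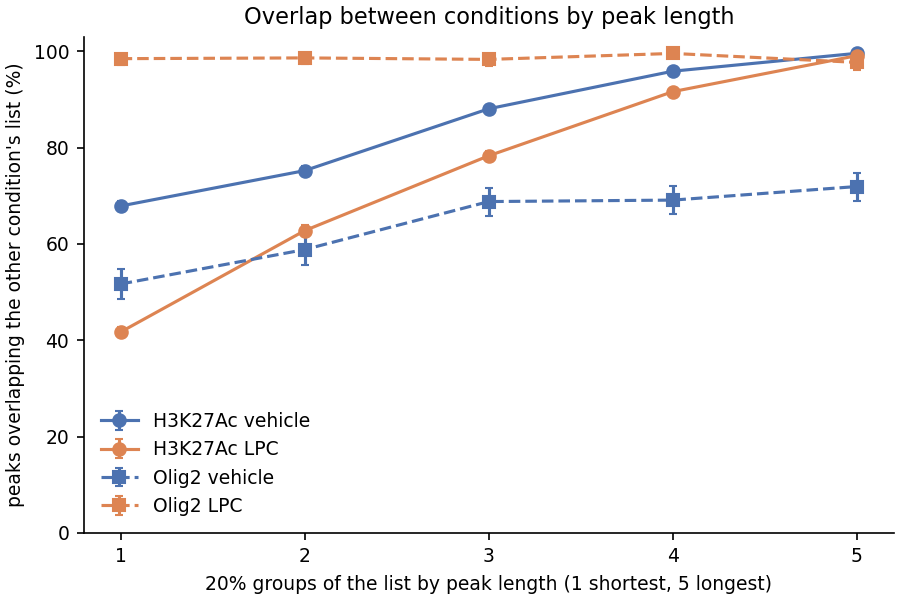
Share of peaks that overlap the other condition's list (vertical axis, percent) by group of 20% of the list in peak length (horizontal axis, 1 shortest to 5 longest), for the 4 lists, with exact 95% binomial intervals. The H3K27Ac shares reach 99.6% and 99.1% in the longest group, whereas that of vehicle Olig2 peaks reaches 71.9%.

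The longest LPC-only H3K27Ac peaks lay on chromosome 3 (41045493 to 41049385, 3893 bp), chromosome 13 (19189406 to 19193227, 3822 bp), chromosome 14 (102724185 to 102726924, 2740 bp), chromosome 13 again (47191497 to 47193760, 2264 bp) and chromosome 9 (88686464 to 88688658, 2195 bp). None of these held an Olig2 peak in either condition. The longest vehicle-only H3K27Ac peaks lay on chromosome 4 (75900388 to 75904307, 3920 bp), chromosome 14 (4364169 to 4368069, 3901 bp), chromosome 13 (30441605 to 30443657, 2053 bp), chromosome 12 (7030285 to 7031897, 1613 bp) and chromosome 20 (42275820 to 42277376, 1557 bp). The chromosome 14 peak lay under the vehicle-only Olig2 peak described above, and the other 4 held no Olig2 peak.

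The longest shared H3K27Ac peak spanned 18670 bp on chromosome 3 (25643429 to 25662098). The next were on chromosome 10 (58605815 to 58622593), chromosome 2 (12272133 to 12286085, 180277251 to 180288663 and 120955264 to 120966380). Peaks of the LPC list covered 18612 bp of the chromosome 3 peak. All of these except the first chromosome 2 peak held Olig2 peaks in both conditions.

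The ratio of LPC-only to vehicle-only H3K27Ac peaks was higher on X than on any autosome. X held 331 LPC-only and 85 vehicle-only peaks, a ratio of 3.89. The autosomes together gave 1.68, with the lowest at 1.45 on chromosome 15 and the highest at 2.02 on chromosome 16. The X list grew from 767 to 985 peaks, while the autosome with the largest relative growth, chromosome 16, went from 1130 to 1186 peaks. Among peaks at or above the median length of each list, X gave 1.32 and the autosomes 1.44. When such peaks were compared with the whole of the other list, X held 25 LPC-only and 5 vehicle-only peaks, a ratio of 5.0, against 1.95 for the autosomes and 3.78 for the highest of them. With 50% of each peak required to overlap, the ratio was 1.84 on X and 0.98 on the autosomes, and 1.72 and 1.29 when peaks were also joined within 1 kb. That rule matches peaks 1 to 1, so the counts on a chromosome differ only as its list lengths do. These ratios are therefore no separate check on the X excess. For Olig2, 26 of 47 vehicle peaks on X were kept (55.3%, 40.1 to 69.8), against 64.1% on autosomes, and no LPC-only Olig2 peak lay on X.

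**Figure D3:**
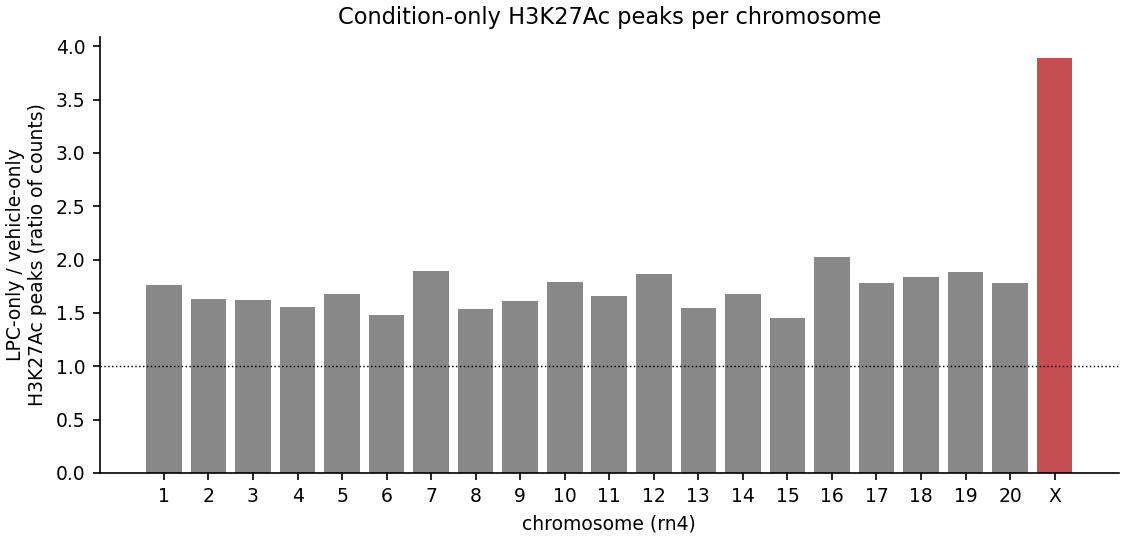
Number of LPC-only H3K27Ac peaks divided by the number of vehicle-only ones (vertical axis, linear, from 0) for each rn4 chromosome (horizontal axis); the dotted line marks equal numbers. X stands at 3.89 and the 20 autosomes lie between 1.45 and 2.02.

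Olig2 peaks lay on H3K27Ac peaks in similar shares in the full lists of both conditions. In vehicle, 2955 of 4965 Olig2 peaks (59.5%, 58.1 to 60.9) overlapped an H3K27Ac peak. In LPC, 1962 of 3229 did (60.8%, 59.1 to 62.5). With all 4 lists limited to peaks at or above their median length, the shares were 66.0% (64.1 to 67.9) in vehicle and 68.7% (66.4 to 71.0) in LPC. The highest values among 1000 shifts were 4.17% and 5.26% for the full lists, and 4.22% and 5.56% for the lists limited by length. Conversely, 10.6% of vehicle and 6.17% of LPC H3K27Ac peaks carried an Olig2 peak of the same condition.

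Sites that were missing from the LPC Olig2 list were acetylated about as often as sites that were kept. Of vehicle-only Olig2 peaks, 58.2% overlapped a vehicle H3K27Ac peak and 58.8% an LPC H3K27Ac peak. For shared Olig2 peaks the values were 60.3% and 60.7%. The differences (vehicle-only minus shared) were -2.04 percentage points (-4.90 to 0.80) and -1.92 points (-4.77 to 0.91). Vehicle-only H3K27Ac peaks underlay 120 of 1785 vehicle-only Olig2 peaks (6.72%) and 196 of 3180 shared ones (6.16%), a difference of 0.56 points (-0.83 to 2.04). With 50% of each peak required to overlap, that difference was 1.79 points (0.17 to 3.50). LPC-only H3K27Ac peaks underlay 7.28% of vehicle-only and 6.51% of shared Olig2 peaks.

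Within 1 kb either side of the Olig2 midpoint, H3K27Ac peaks covered a mean of 789 bp in vehicle and 837 bp in LPC at vehicle-only Olig2 sites. At shared Olig2 sites the means were 847 and 916 bp. LPC coverage exceeded vehicle coverage at 679 of the 1785 vehicle-only sites, was below it at 399 and equalled it at 707. At the 3180 shared sites these counts were 1280, 607 and 1293. Among pooled acetylated regions with peaks of both conditions, LPC peaks covered more bases in 64.3% of those with vehicle-only Olig2 peaks alone. The share was 69.5% with shared Olig2 peaks alone and 72.4% with no vehicle Olig2 peak. Regions without a vehicle Olig2 peak were shorter (median span 1231 bp against 1839 and 1958 bp). Of the 48 LPC-only Olig2 peaks, 31 (64.6%, 49.5 to 77.8) overlapped a vehicle H3K27Ac peak, 33 (68.8%, 53.7 to 81.3) an LPC H3K27Ac peak and 4 (8.33%, 2.32 to 20.0) an LPC-only one.

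**Figure D4:**
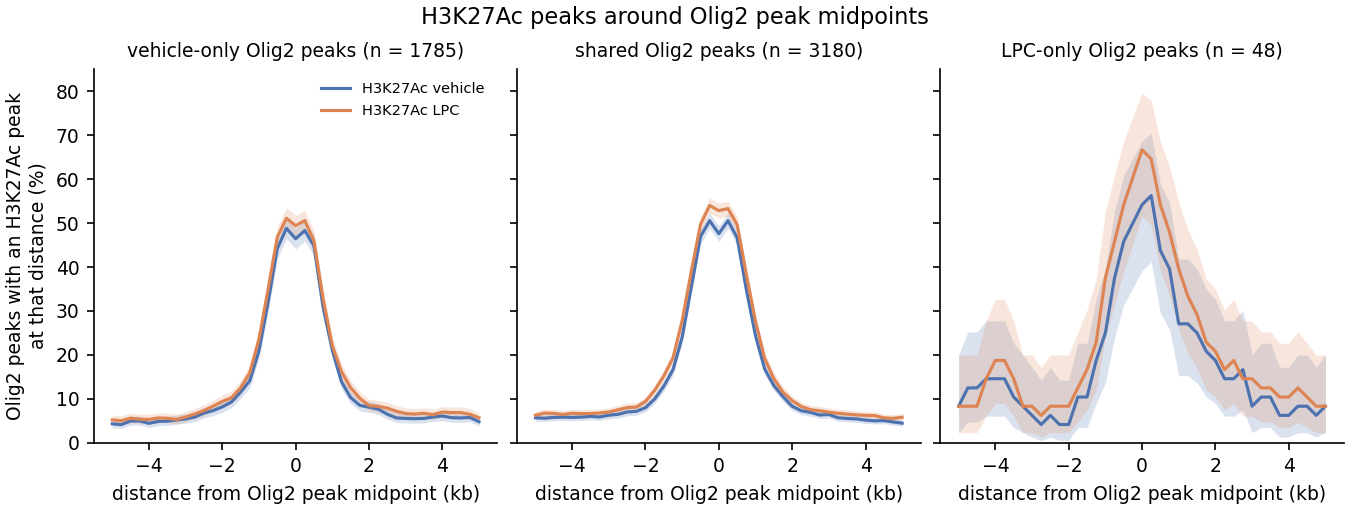
Share of Olig2 peaks (vertical axis, percent) with an H3K27Ac peak of the vehicle (blue) or LPC (orange) list at each distance from the Olig2 midpoint (horizontal axis, kb), for vehicle-only, shared and LPC-only Olig2 peaks; bands are exact 95% binomial intervals. At the midpoint the vehicle and LPC shares are 46.4% and 49.4% for vehicle-only, 47.6% and 52.8% for shared, and 54.2% and 66.7% for the 48 LPC-only Olig2 peaks.

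LPC-only acetylated sites carried Olig2 less often than shared ones. An LPC Olig2 peak lay on 231 of 9803 LPC-only H3K27Ac peaks (2.36%, 2.07 to 2.68) and on 7.47% (7.17 to 7.77) of shared peaks of the LPC list. Peaks with Olig2 were longer, with a median of 1288 bp against 803 bp. Of the 2390 LPC H3K27Ac peaks with Olig2, 9.67% were LPC-only, whereas length-matched draws without Olig2 gave a mean of 14.7% and a lowest value of 12.7%. With peaks joined within 1 kb the values were 8.29% and 11.5% (lowest draw 9.74%).

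In the vehicle list, 5.82% (5.23 to 6.46) of vehicle-only and 11.5% (11.1 to 11.8) of shared H3K27Ac peaks carried a vehicle Olig2 peak. Of the vehicle H3K27Ac peaks with Olig2, 8.06% were vehicle-only, against a matched mean of 9.75% (lowest draw 8.59%). With joined peaks, that contrast was within the range of the draws (8.13% against draws of 6.67 to 9.37%).

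Joining H3K27Ac peaks within 12.5 kb gave 4484 vehicle and 4182 LPC domains of at least 3 peaks. Of these, 15 vehicle domains (0.33%) held no LPC peak and 54 LPC domains (1.29%) held no vehicle peak. A vehicle Olig2 peak lay in 62.7% (55.7 to 69.3) of the 209 vehicle domains of 10 or more peaks and in 11.1% (10.6 to 11.6) of those of 1 or 2 peaks. Per megabase of domain, the latter held more vehicle Olig2 peaks, 67.8 against 26.7.

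The longest vehicle domain spanned 133 kb on chromosome 20 (43500635 to 43633968) with 39 peaks. LPC peaks covered 69.8 kb of it, and vehicle peaks 61.0 kb. The longest LPC domain spanned 105 kb on chromosome 11 (58680507 to 58785795) and held 10 vehicle but 5 LPC Olig2 peaks. These 2 domains were among the 5 longest of both conditions. The others in vehicle were on chromosome 7 (123595147 to 123704122), chromosome 3 (34428019 to 34527927) and chromosome 1 (208398346 to 208492192). In LPC they were on chromosome 5 (70874234 to 70973679), chromosome 1 (157950740 to 158043486) and chromosome 12 (9949173 to 10037972). Of the 100 longest vehicle domains, 59 overlapped one of the 100 longest LPC domains.

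The share of vehicle Olig2 peaks kept after LPC was close to the same inside and outside acetylated domains. It was 63.2% (61.0 to 65.3) outside any vehicle domain, 64.6% (62.1 to 67.1) in domains of 1 or 2 peaks, 64.1% (61.4 to 66.8) in domains of 3 to 9 peaks and 66.8% (60.5 to 72.7) in domains of 10 or more. Olig2 peaks on a vehicle H3K27Ac peak were kept in 64.8% and those off one in 62.9%, a difference of 1.95 points (-0.76 to 4.68).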

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

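The comparison of Olig2 classes with H3K27Ac classes was planned, but the limit set for it and the tests of peak length in this part were chosen after the results had been seen. The antibodies moved in opposite directions between the same conditions: the length covered by H3K27Ac peaks in LPC was 1.21 times that in vehicle, and the length covered by Olig2 peaks 0.615 times. The mean peak length was 885 bp in vehicle and 1077 bp in LPC for H3K27Ac, and 1144 and 1083 bp for Olig2. With 1 library on each side this difference was not tested.

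For Olig2, the shorter and almost nested LPC list is what fewer occupied sites would give, and also what a shallower or less enriched LPC library, or a stricter call, would give. Loss of sites together with their acetylation was left open. Vehicle-only Olig2 peaks overlapped vehicle-only H3K27Ac peaks 0.56 percentage points more often than shared ones (-0.83 to 2.04). Under the reciprocal overlap the difference was 1.79 points (0.17 to 3.50). The limit for this difference was set after the results had been seen. A deeper LPC H3K27Ac library could also hide lost acetylation, so the comparison cannot decide. In the lists as called, 6.72% of vehicle-only and 6.16% of shared Olig2 peaks lay on a vehicle-only H3K27Ac peak. These values describe the presence of peaks, not signal. Lower yield cannot be told apart from lower occupancy here: 71.9% of the longest 20% of vehicle Olig2 peaks were kept, but length is not a measured strength, and the lists hold neither scores nor depths.

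For H3K27Ac, splitting of peaks in the vehicle list may account for part of the difference in peak length. Joining peaks within 1 kb lowered the LPC over vehicle ratio of the median length from 1.22 to 1.12 and that of the mean length from 1.22 to 1.08, and whether splitting explains the rest stays open, since joining also merges neighbouring peaks that were never split. A deeper or better enriched LPC library cannot be told apart from wider acetylation, since no depth or score is at hand. LPC-only peaks had a median of 531 bp against 1003 bp for shared LPC peaks, which either explanation could give. An effect of LPC itself stays open and untested for both antibodies.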

How the results depend on the processing

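The filters on length, the joining of peaks, joining with the reciprocal overlap and the shifts of 50 to 500 kb were chosen after seeing the data. No paired analysis was possible because each antibody and condition had 1 library, and for the same reason no replicate could be left out. Score filters and gene lists were not run. With 50% of each peak overlapping, condition-only counts were 16891 (vehicle) and 16710 (LPC) for H3K27Ac and 92 LPC-only for Olig2. Olig2 then lay on H3K27Ac in 34.5% (vehicle) and 34.9% (LPC). A stricter overlap can only raise condition-only counts and lower such shares. The same number of H3K27Ac peaks, 22011, was matched in each list, so the 2 remainders differ only as the list lengths do. Joining within 1 kb first gave 109 LPC-only Olig2 peaks and shares of 33.7% and 31.2%. Counting peaks within 1 kb as overlapping left 3618 vehicle-only H3K27Ac peaks, and joining alone left 6443 LPC-only ones. Among peaks at or above the median length of each list, vehicle-only and LPC-only counts were 3318 and 4775 for H3K27Ac and 1134 and 263 for Olig2, Olig2 lay on H3K27Ac in 66.0% and 68.7%, and domains of at least 3 peaks numbered 1605 and 1406, all with fewer peaks compared. Requiring that length of condition-only peaks alone left 714 and 1409 for H3K27Ac and 760 and 24 for Olig2. With equal list lengths, Olig2 gave 995 and 994 by construction, and 72.6% of the vehicle Olig2 peaks kept lay on H3K27Ac; this share is not comparable with the LPC one, since of the Olig2 lists the vehicle one alone was cut to its longest peaks. The other 35 values of the main comparisons stayed within 1.5 times the count or within the counting interval. The fold over shifted positions moved in 23 of 32 alternatives and was lowest at 12.6 for LPC Olig2 on H3K27Ac within 1 kb. The unknown read depth limits every statement about a missing peak.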

Other observations

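LPC-only acetylated domains were mostly single peaks. Of 3748 LPC domains without any vehicle peak, 3229 were 1 peak, and of 2151 vehicle domains without any LPC peak, 1979 were. The LPC-only domains held at most 4 peaks, and the 3 with the longest covered length among the 6 with 4 peaks lay on chromosome 7 (60781465 to 60785458), chromosome 10 (37380105 to 37383112) and chromosome 1 (59370067 to 59372589), each with no Olig2 peak in either condition. The vehicle-only domains held at most 3 peaks, and the 3 with the longest covered length among the 15 with 3 peaks lay on chromosome 2 (107643174 to 107663730), chromosome 20 (8466962 to 8483691) and chromosome 3 (88522508 to 88531176), each with no Olig2 peak. The LPC domains named here spanned 3994, 3008 and 2523 bp, of which peaks covered 3542, 2720 and 2287 bp. The vehicle domains named spanned 20557, 16730 and 8669 bp, with 2354, 2137 and 1764 bp covered. A higher number of peaks thus did not mean a wider domain. These regions were picked after their values had been seen.

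Vehicle H3K27Ac peaks were slightly sparser at the midpoint of shared Olig2 sites than 250 bp to either side, with 47.6% (45.8 to 49.3) at the midpoint and 50.5% and 50.6% beside it. In the LPC list the values were 52.8%, 54.0% and 53.3%. At vehicle-only Olig2 sites the vehicle values were 46.4%, 48.8% and 48.3%, and the LPC values 49.4%, 51.1% and 50.6%. Within a class the shares come from the same sites, so their separate intervals, which overlap, do not measure the dip. Neither the dip nor its difference between conditions was tested.

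The excess of LPC-only H3K27Ac peaks on X was a pattern noticed in the data. The Olig2 test of it was chosen after its result had been seen, while the tests of the median length ratio and of the windows were not. A few local clusters were argued against: all 17 windows of 10 Mb on X had a ratio above the autosomal 1.68. The top 3 windows held 31.3% of the surplus of LPC-only over vehicle-only peaks on X. That surplus includes the part that the autosomes also showed. Some windows held few condition-only peaks, such as 5 LPC-only and 1 vehicle-only at 160 to 170 Mb. One candidate explanation is more X copies in the LPC chromatin, from a different mix of male and female pups, and the tests leave it open. Both predictions assume that added X copies are acetylated and bound by Olig2 like the others, which was not examined. If they are not, neither test bears on this explanation. For H3K27Ac, the median log2 length ratio (LPC over vehicle) of X regions present in both lists was 0.227 (bootstrap 95% interval 0.18 to 0.27). More X copies were predicted to put X above every autosome. That was not met, since 1 autosome stood higher (0.232), but the interval includes that value. The total length covered in LPC over vehicle was 1.34 on X and 1.18 to 1.24 on the autosomes. That total was not among the tests set beforehand. It includes the LPC-only peaks that made the pattern, so it restates the excess and does not bear on its cause. For Olig2, more X copies were predicted to raise the share kept on X above that on the autosomes. The share was lower instead, 55.3% against 64.1%, but its interval (40.1 to 69.8) includes the autosomal value. The labels do not give the sex of the pups or say whether both antibodies were used on the same chromatin. An effect of LPC on X-linked chromatin and a deeper or better enriched LPC library were not tested as causes of the excess. Neither can therefore be told apart from more X copies. The excess also depended on how peaks were filtered by length. With both lists limited to peaks at or above their median length, X gave 1.32 and the autosomes 1.44. When such peaks were compared with the whole of the other list, X gave 5.0 and the autosomes 1.95.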
